A study of Homo sapiens with 12 samples.

How the data were processed

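RNA sequencing of 12 libraries from 2 established human tumour lines was re-analysed from the deposited tables. KYSE140 is an oesophageal squamous cell carcinoma line and LN229 is a glioblastoma line. Each line had 3 libraries of cells kept in 0.2% DMSO, the solvent control, and 3 of cells given 0.5 µM parimifasor, a small molecule described as acting on the mitochondrial ATP synthase, both for 36 h. Per the labels, polyadenylated RNA was made into strand-specific paired-end libraries and sequenced on an Illumina NovaSeq. The aligner and the counting program are not given in the sources used here. The processing notes name hg38 and also the mouse build GRCm38, while the gene identifiers in the tables were all human Ensembl identifiers. A treatment note in the labels describes siRNA transfection of A549 cells, a lung carcinoma line, which contradicts every other label. The groups were taken from the sample descriptions, and the cell line labels were checked through lineage marker genes.

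The deposited count table holds raw read counts per gene, with no normalization by the authors. The second deposited table holds FPKM, fragments scaled to gene length and library size, computed by the authors. The ratio of FPKM to count gave the same length in all libraries, to within 1e-06 of its size, and a whole number, to within 1e-04, for 100% of 36069 genes, so the FPKM table carries the same information as the counts, and it served only as an alternative. The count table had 40705 gene identifiers, of which 40617 matched a current symbol and 88 did not. Coordinates are those of GENCODE 29 on GRCh38 and cover the whole gene, introns and UTRs included. Total counts per library ran from 34.38 to 49.24 M. A gene with no count in a library can be excluded only down to 3 counts of that total, a limit that covers counting error alone, since reads without molecular identifiers are not independent molecules.

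Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 4 groups, which left 21747, and scaled by TMM. A quasi-likelihood model with robust estimation and 1 term per group was fitted to all 12 libraries. Contrasts were parimifasor against DMSO in each line, the difference between these responses as an interaction (KYSE140 minus LN229), and KYSE140 against LN229 in DMSO. Tests were two-sided, p-values were adjusted over all genes tested by Benjamini-Hochberg, and a gene was called below an adjusted p of 0.05. Values per gene are counts scaled to library size (CPM) with SD over n = 3, and log2 fold changes with the standard error (SE) of the model. Standard errors and tests measure only the spread between these libraries, since the labels number the replicates without saying that they are separate cultures.

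Gene lists, 47 of them, covered mitochondrial, stress, metabolic, proliferation, death, inflammatory, signalling and lineage genes. Of the listed names, 2 had no match, H2AC18 and TGM3. Each list was compared with all other genes by camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists of a contrast. The correlation estimated from the residuals was an alternative, and fry tested whether the genes of a list moved together, without reference to other genes. Called members were counted over all genes and adjusted over the list alone.

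The genes named in the text followed a rule. For each line it took called genes with all 3 treated libraries on the same side of all 3 DMSO libraries, a mean of at least 5 CPM in 1 of both groups and a symbol that was no clone name. Of these, up to 12 with the highest and 12 with the lowest fold change were named. It added up to 4 members with the smallest p from each called list, and from the mitochondrially encoded and ATP synthase lists whatever their test, and up to 6 genes each way for the difference. The text describes a part of the genes so chosen. The groups, contrasts, tests, lists, rule for named genes and most alternative settings were fixed before the data were examined.

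These alternative settings were RLE, upper quartile and library size scaling, no filter or a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma-trend on log2 FPKM with pseudocounts of 1 and 0.1, each line fitted alone, leaving out each library in turn, and the replicate number within each line as a block. The mean response over both lines, a fit on replicates 1 and 2 alone, a correction for gene length and GC content, available for 97.91% of genes, the same correction together with the block, and leaving out genes within reach of the other line's reads were chosen after the data had been seen. A gene counted as within reach when its level was below 3% of that in the other line. That share, and the limits of 100 CPM and 1.5% used to measure other-line reads, were also set after the data had been seen. Overlap of calls was tested by Fisher's exact test and library shares by two-sided exact permutation tests, for which 3 against 3 libraries allow no p below 0.1.

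Replicate numbers turned out to link libraries. Residual correlations within a line were 0.157 to 0.352 between libraries with the same number and -0.29 to 0.169 otherwise, and 11 of 12 libraries correlated best with their own number. The biological coefficient of variation was 22.5%, or 14.1% with the block. The fit without the block remained the primary one, as planned.

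The model was tested on simulated data with 21000 genes and the same design. Of 67 genes shifted by 2-fold, 59.7% were recovered in KYSE140 and 64.2% in LN229. At 1.5-fold the shares were 17.9% and 14.9%, and at 4-fold 92.4% in both. In these fits 9 unchanged genes were called in each line, and with the block 12 in KYSE140 and 19 in LN229. A mitosis list shifted by 1.5-fold was found, and camera called 0 of the 46 other lists. The simulated genes varied independently of each other, and no replicate effect was simulated. Other splits of the real libraries of a line called a median of 14 lists in KYSE140 and 16 in LN229. The simulation therefore does not measure how often lists are called falsely in these libraries, nor what the block does there.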

Results

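Poly(A) RNA was sequenced from KYSE140 oesophageal squamous carcinoma cells and LN229 glioblastoma cells, each in 3 libraries with 0.2% DMSO and 3 with 0.5 µM parimifasor for 36 h. The series presents parimifasor as a candidate antitumour compound, and the 4 groups of 3 address how each line's transcripts respond to it. Total counts were 42.1 ± 4.06 M (SD, n = 3) in KYSE140 DMSO and 41.72 ± 6.71 M in treated KYSE140. LN229 had 47.01 ± 2.99 M in DMSO and 43.06 ± 4.58 M with the compound. The lowest library held 34.38 M and the highest 49.24 M.

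The first comparison, between the lines in DMSO, checked the identity of the cells. KYSE140 carried the squamous programme. KRT5, a basal keratin (chromosome 12, 52514575 to 52520687), stood at 3860 ± 1090 CPM (SD, n = 3) against 23.7 ± 5.07 in LN229. TP63, the transcription factor of squamous epithelium, stood at 556 ± 92.2 against 4.88 ± 0.934 CPM, and E-cadherin, CDH1, at 390 ± 48.3 against 2.20 ± 0.227. LN229 carried glial and neural markers, with SOX10 at 947 ± 112 CPM against 6.63 ± 1.14 in KYSE140 and the intermediate filament genes NES and VIM at 1620 ± 39.9 and 955 ± 31.4 against 12.1 ± 0.760 and 51.7 ± 2.70. Other glioma markers went the other way. SLC1A3 was at 5.48 ± 1.56 CPM in LN229 against 141 ± 18.2 in KYSE140, and SOX9, PTPRZ1, AQP4 and CHI3L1 also had higher means in KYSE140. GFAP was at only 2.29 ± 0.515 CPM in LN229. Of 21 squamous markers, 20 exceeded 5 CPM in KYSE140 and 9 in LN229, and of 21 glioma markers 9 and 16 did. Of 20 markers of A549 cells, 7 exceeded 5 CPM in each line, and of 24 squamous differentiation markers 4 and 1 did. For fibroblast markers, 12 in number, the counts were 3 and 6, and of 10 endothelial markers 1 exceeded 5 CPM in each line. The median of 15 leukocyte markers was 0.275 CPM in KYSE140 and 0.112 CPM in LN229. In all, 13757 of 21747 genes differed between the lines, 6938 higher and 6819 lower in KYSE140.

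Transcripts abundant in the other line were present at low levels in every group. The genes used were chosen to lie under 1.5% of the other line's level, so a low share follows from the choice. Whether the reads came from the other line or from low expression of the line's own was not tested. Over 51 genes with at least 100 CPM in LN229 and under 1.5% of that in KYSE140, KYSE140 libraries held 0.846% ± 0.129 (SD, n = 3) of the LN229 level in DMSO and 0.649% ± 0.430 with parimifasor (exact permutation p = 0.5). Over 54 genes chosen the other way, LN229 libraries held 0.729% ± 0.167 and 0.931% ± 0.107 of the KYSE140 level (exact permutation p = 0.3). The median log2 fold change of these genes was -0.47 in KYSE140, with 47 of 51 lower, and 0.34 in LN229, with 51 of 54 higher. The lower share in treated KYSE140 came from parimifasor replicate 3 (0.204%), replicates 1 and 2 being at 1.06% and 0.68%, and without it the treated mean was 0.87%, above that of DMSO.

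Replicate 3 stood apart in all 4 groups. Interferon-stimulated genes, 29 of which were measured, averaged 4.57 log2 CPM in KYSE140 DMSO replicate 3 against 0.692 in replicates 1 and 2, and 3.65 against 0.873 in treated KYSE140. In LN229 the averages were 7.26 against 2.5 in DMSO and 5.59 against 2.55 with the compound. A term for replicate 3, chosen after these values were seen, called 1275 genes with 684 higher. Among the higher were 28 of the 29 interferon-stimulated genes, 12 of 18 immediate early genes and 12 of 21 unfolded protein response genes. The last list holds endoplasmic reticulum chaperones and other genes such as XBP1 and HERPUD1.

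**Figure D1:**
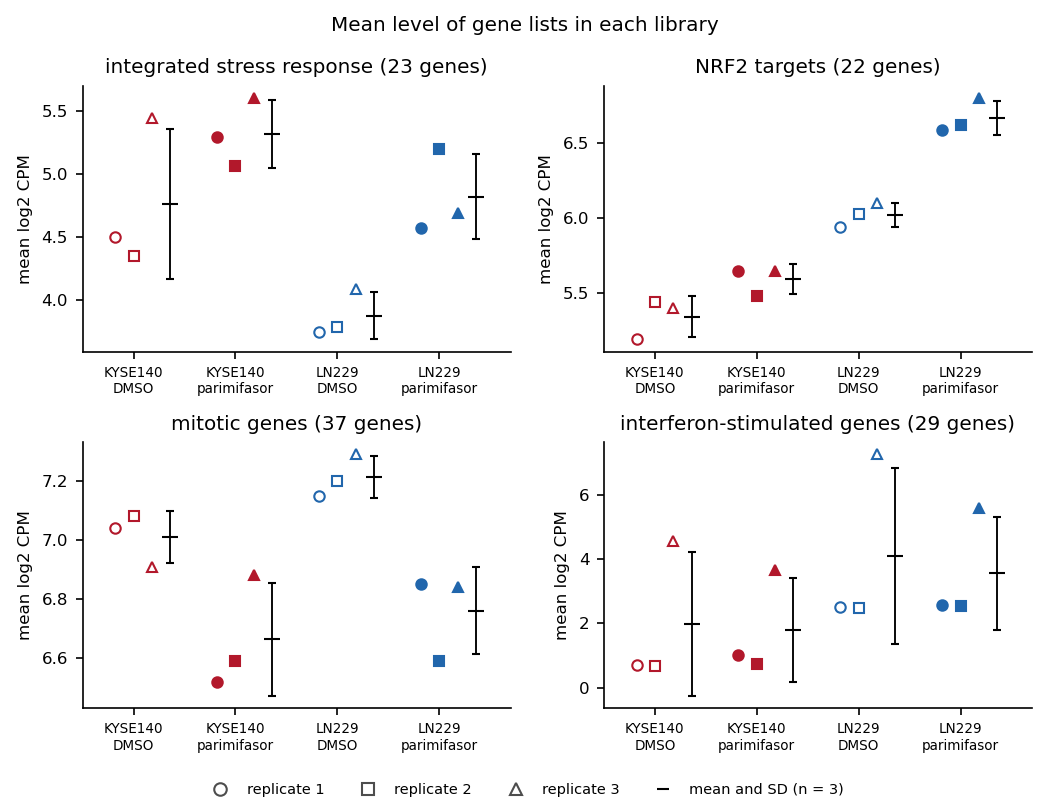
Mean log2 CPM of 4 gene lists in each of the 12 libraries, by line and treatment on the x axis, with symbols for the replicate number and bars for mean and SD (n = 3). Interferon-stimulated genes stand at 4.57, 3.65, 7.26 and 5.59 in the replicate 3 libraries of the 4 groups, above the other libraries of the same group, and the mitotic genes of treated KYSE140 stand at 6.52, 6.59 and 6.88.

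In KYSE140, parimifasor raised a small set of metabolic and cytoskeletal genes. ASS1, the argininosuccinate synthase of arginine synthesis (ENSG00000130707, chromosome 9, 130444929 to 130501274), rose 2.67-fold, from 74.4 ± 6.92 to 199 ± 48.9 CPM (SD, n = 3; log2 fold change 1.42 ± 0.202 SE, adjusted p = 0.0254). The aldo-keto reductase genes AKR1C1 (ENSG00000187134, chromosome 10, 4963253 to 4983283) and AKR1C2 (ENSG00000151632, chromosome 10, 4987400 to 5018031) are neighbours and NRF2 targets. They rose 2.14-fold, from 22.9 ± 3.05 to 49.0 ± 11.1 CPM, and 2.10-fold, from 42.1 ± 6.32 to 88.6 ± 14.7 CPM, with adjusted p of 0.0254 and 0.0202. Reads can be shared among such close paralogs. The third gene of the cluster, AKR1C3, had a log2 fold change of -0.13 ± 0.171 (adjusted p = 0.867), which does not tell AKR1C1 and AKR1C2 apart. TUBB2B, a beta-tubulin, rose 1.88-fold (chromosome 6, 3224261 to 3231730, adjusted p = 0.0254). CHPF, a chondroitin polymerizing factor, and PCDH1, a protocadherin, rose 1.60-fold and 1.44-fold. GASK1B, a Golgi kinase family gene (ENSG00000164125, chromosome 4, 158124474 to 158173318), fell 2.14-fold, from 50.8 ± 4.67 to 23.7 ± 2.56 CPM (log2 fold change -1.10 ± 0.143 SE, adjusted p = 0.0202). PMEPA1, an inhibitor of TGF-beta signalling, fell 1.62-fold (adjusted p = 0.0455) and N-cadherin, CDH2, 1.48-fold (adjusted p = 0.0311).

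In all, edgeR called 10 genes in KYSE140, 7 higher and 3 lower, not all of them named here, and 5 of the 10 changed at least 2-fold, 4 higher and 1 lower. An unadjusted p below 0.05 was reached by 2158 genes, where 1087 would be expected by chance. With the replicate number as a block, 217 genes were called, 142 higher and 75 lower, the 10 among them. The count depended on single libraries. It was 0 without DMSO replicate 1 or without parimifasor replicate 1 (2190 and 1285 genes at an unadjusted p below 0.05). It was 1 without DMSO replicate 2 or parimifasor replicate 2, 39 without DMSO replicate 3 and 116 without parimifasor replicate 3. Each of the 10 calls ended in at least 1 of these refits, the highest adjusted p being 0.0728 for GASK1B, 0.0852 for AKR1C2, 0.0922 for AKR1C1, 0.12 for TUBB2B, 0.129 for CHPF, 0.218 for CDH2, 0.219 for ASS1 and 0.35 for PCDH1 and PMEPA1.

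As groups, proliferation genes were lower and stress and metabolic genes higher in treated KYSE140. The calls of these 11 lists rest on the preset correlation, and with an estimated correlation their adjusted p ran from 0.711 to 0.972. The KYSE140 libraries can be split 3 against 3 in 10 ways, a comparison chosen after the data had been seen. The real split gave the smallest camera p for 3 of the 11 lists, amino acid synthesis, mitotic genes and NRF2 targets. For these 3 another split came close, with unadjusted camera p of 0.00469 against 0.00442, 5.38e-18 against 3.77e-18 and 0.000134 against 8.72e-05. A p as small came from 3 of the 10 splits for integrated stress response genes and from 5 for ribosomal proteins, the real one included. Mitotic genes fell, 36 of 37 being lower with a median log2 fold change of -0.36 (camera adjusted p = 1.77e-16). Their mean log2 CPM was 7.04 and 7.08 in DMSO replicates 1 and 2 and 6.52 and 6.59 in parimifasor replicates 1 and 2, but 6.91 and 6.88 in the replicate 3 libraries. TOP2A, the topoisomerase of dividing cells, was at 751 ± 117 CPM in DMSO and 521 ± 27.7 with parimifasor, and the spindle gene ASPM at 356 ± 30.1 and 247 ± 38.7, each with an edgeR adjusted p of 0.125. DNA replication genes (33 of 36 lower, adjusted p = 1.07e-06), replication-dependent histone genes (13 of 15 lower, 0.000289), DNA repair genes (22 of 26 lower, 0.00405) and ribosome biogenesis genes (24 of 28 lower, 8.58e-05) fell as well. The histone genes were low in these libraries of polyadenylated RNA, with a mean log2 CPM of 0.566 to 1.35 per KYSE140 library. Targets of the integrated stress response, the ATF4 programme, rose, with 21 of 23 higher and a median of 0.40 (adjusted p = 2.66e-05). Their mean log2 CPM was 4.50, 4.35 and 5.44 in DMSO replicates 1 to 3 and 5.29, 5.06 and 5.60 with parimifasor, so that DMSO replicate 3 lay above treated replicates 1 and 2. Its member GDF15, a stress cytokine, was at 8.79 ± 5.24 and 19.6 ± 5.15 CPM, with an adjusted p of 0.401. Genes of amino acid and one-carbon synthesis (13 of 18 higher, adjusted p = 0.0189), of the hypoxia response (14 of 20 higher, 0.00492), NRF2 targets (17 of 22 higher, 0.000585) and ribosomal proteins (38 of 41 higher, 0.000289) also rose. ASNS, asparagine synthetase, was at 16.9 ± 10.3 and 41.5 ± 8.66 CPM, and VEGFA at 86.2 ± 20.8 and 145 ± 17.9. The glioma list fell (16 of 21 lower, adjusted p = 0.0189), and 10 of its genes lay within reach of LN229 reads. Without genes within reach, its adjusted p was 0.187. The genes within reach had a median log2 fold change of -0.47 and the others one of -0.24, among them CDH2, called in KYSE140 at 74.3 and 50.2 CPM in DMSO and parimifasor.

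With an estimated correlation 2 of 47 lists in KYSE140 had an unadjusted p below 0.05. By fry the 11 lists had adjusted p of 0.213 to 0.735, with 6 below 0.05 unadjusted. Within replicate numbers, the mean log2 CPM moved in 1 direction in all 3 pairs for 7 of the 11 lists. DNA replication and ribosome biogenesis genes rose slightly in replicate 3 (by 0.054 and 0.066), ribosomal proteins fell in replicate 2 (change -0.080), and glioma genes rose in replicate 1 (by 0.050) and fell in replicate 3 (change -1.29). Over all genes the called members were AKR1C1, AKR1C2 and CDH2. With the block, ABCC3 (0.0128), OSGIN1 (0.0235) and FTL (0.0305) of the NRF2 list, NDRG1 (0.0285), P4HA2 (0.0372) and VEGFA (0.0434) of the hypoxia list, ASPM (0.0434) and KIF18A (0.0451) of the mitotic list, DDIT4 (0.0227) and UTP20 (0.0265) were called too. Adjusted over the list alone, 20 mitotic genes were lower, as were 3 histone and 2 ribosome biogenesis genes. On the same basis 5 NRF2 targets and 3 hypoxia genes were higher, and of the amino acid synthesis genes 3 were higher and 1 lower. The amino acid synthesis call ended without DMSO replicate 1 (adjusted p = 0.148) or parimifasor replicate 3 (0.214), and the hypoxia call without DMSO replicate 1 (0.0879). The ribosomal protein call ended without DMSO replicate 3 (0.12) or parimifasor replicate 3 (0.227), and those of DNA repair and glioma genes without parimifasor replicate 3 (0.0669 and 0.621). With the block, immediate early genes (0.0201) and MAPK feedback genes (0.00251) were called too, both higher, with an adjusted p of 0.786 for each with an estimated correlation in that fit. With replicates 1 and 2 alone the calls of amino acid synthesis (0.141) and glioma genes (0.784) ended, and the direction of the ribosomal proteins turned (0.844).

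Among the genes named for largest change in LN229, the highest fold changes were those of SPRR2D and LCN2. Both were at a low level in DMSO, and the rule required a mean of at least 5 CPM in a group. LCN2, the iron-carrier binding protein lipocalin (ENSG00000148346, chromosome 9, 128149071 to 128153455), rose 18.1-fold, from 0.902 ± 0.533 to 16.3 ± 1.09 CPM (SD, n = 3; log2 fold change 4.17 ± 0.395 SE, adjusted p = 0.000184). SPRR2D, a cornified envelope gene with close paralogs (ENSG00000163216, chromosome 1, 153039725 to 153041931), rose 18.4-fold, from 1.67 ± 1.33 to 30.6 ± 9.59 CPM (4.20 ± 0.486, adjusted p = 0.00168). SQSTM1, the autophagy receptor p62 (ENSG00000161011, chromosome 5, 179806398 to 179838078), rose 2.75-fold, from 275 ± 19.7 to 758 ± 94.7 CPM (1.46 ± 0.133, adjusted p = 0.000184). FTL, the ferritin light chain (ENSG00000087086, chromosome 19, 48965301 to 48966878), rose 2.48-fold, from 1350 ± 121 to 3350 ± 667 CPM (1.31 ± 0.145, adjusted p = 0.000504). GDF15 (ENSG00000130513, chromosome 19, 18374731 to 18389176) rose 6.60-fold, from 46.1 ± 13.9 to 304 ± 73.6 CPM (2.72 ± 0.428, adjusted p = 0.0312), but its call ended in each refit without 1 LN229 library, with an adjusted p of up to 0.162 without DMSO replicate 1. VEGFA, the angiogenic growth factor (chromosome 6, 43770184 to 43786487), rose 2.85-fold (adjusted p = 0.00168), and the netrin receptor gene UNC5B 7.98-fold, from 0.682 ± 0.199 to 5.44 ± 2.14 CPM (adjusted p = 0.000184). ADM2, BEX2, KRT81, LURAP1L, NEBL, AKNA and AHNAK2 rose by 2.88-fold to 5.99-fold. FLT1, a VEGF receptor gene (chromosome 13, 28300344 to 28495145), fell 1.88-fold, from 194 ± 17.4 to 103 ± 20.2 CPM (adjusted p = 0.0212), and the proliferation marker MKI67 (chromosome 10, 128096659 to 128126385) fell 1.57-fold, from 1400 ± 63.0 to 892 ± 35.3 CPM (adjusted p = 0.0137). Also lower were CEMIP2, LRRK2, CERT1, PTCH1 and the spindle and chromosome genes CENPE, ASPM, KIF14, TOP2A, CENPF and KIF11, by 1.45-fold to 1.74-fold.

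**Figure D2:**
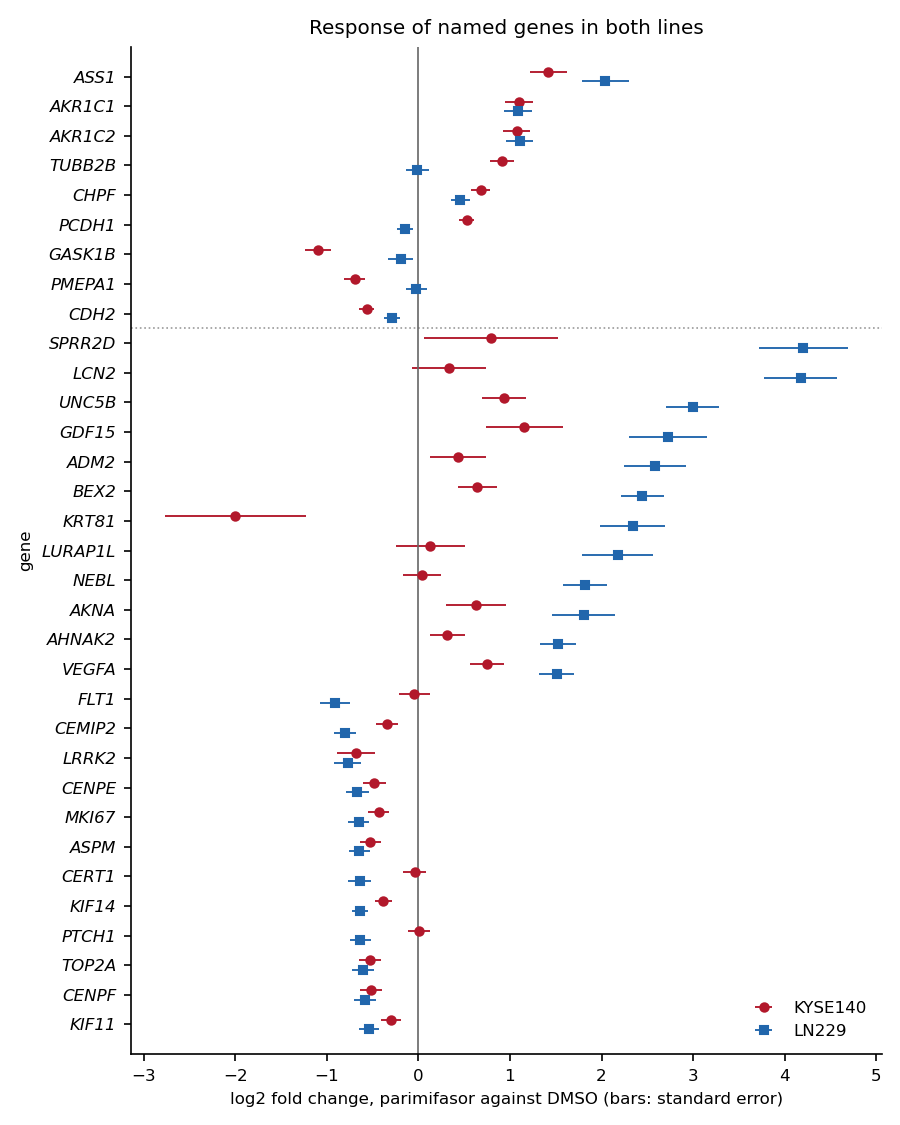
Log2 fold change of parimifasor against DMSO on the x axis for genes named by the rule of largest change in KYSE140 (above the dotted line) and in LN229 (below it), with circles for KYSE140, squares for LN229 and bars for the standard error. AKR1C1 and AKR1C2 lie at 1.10 and 1.07 in KYSE140 and at 1.09 and 1.10 in LN229, while LCN2 lies at 0.33 and 4.17.

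In LN229 edgeR called 122 genes, 102 higher and 20 lower, and 63 of them changed at least 2-fold, 61 higher and 2 lower. An unadjusted p below 0.05 was reached by 2248 genes. With the block the counts were 350 called, 246 higher and 104 lower, and 101 at 2-fold, and 118 of the 122 were among them. The count was 35 without DMSO replicate 1, 52 without DMSO replicate 2, 52 without parimifasor replicate 2 and 56 without parimifasor replicate 3. Of 44 called genes named by the rule, 18 kept their call without each library in turn, among them LCN2, SPRR2D, SQSTM1, FTL, VEGFA, UNC5B and KIF14. The other 26 ended without DMSO replicate 1, 2 or 3 in 26, 22 and 16 cases and without parimifasor replicate 1, 2 or 3 in 5, 23 and 20. The MKI67 call ended without any library but parimifasor replicate 1, at up to 0.0663 without parimifasor replicate 3, and that of FLT1 without DMSO replicate 1 (0.112) or 2 (0.0501) or parimifasor replicate 2 (0.127) or 3 (0.106). Of the 122 genes, 10 lay within reach of KYSE140 reads, among them ASS1 at 0.788 ± 0.270 and 3.24 ± 0.658 CPM, the latter 1.65% of the treated KYSE140 level.

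Ribosomal protein genes, NRF2 targets and integrated stress response genes had the smallest p among the lists that rose in LN229. NRF2 targets rose, with 21 of 22 higher, a median log2 fold change of 0.58, 6 called over all genes and 16 adjusted over the list alone. Their camera adjusted p was 2.49e-16, or 0.0326 with an estimated correlation, and 0.341 when the block was added to that. AKR1C1 went from 59.9 ± 6.58 to 127 ± 11.1 CPM (adjusted p = 0.0032), AKR1C2 from 7.78 ± 0.744 to 16.7 ± 1.13 and the transporter gene ABCC3 from 66.7 ± 3.06 to 166 ± 3.27. NQO1, a canonical NRF2 target named after its value was seen, had a log2 fold change of -0.15 ± 0.126 (adjusted p = 0.782). Integrated stress response genes rose, 23 of 23 being higher with a median of 0.62, 3 called and 11 adjusted over the list alone (adjusted p = 1.37e-11, or 0.245 with an estimated correlation). Amino acid synthesis genes rose in 14 of 18 (5 called, 11 higher and 1 lower adjusted over the list alone, adjusted p = 7.85e-07, or 0.245 with an estimated correlation). Among them were the proline and serine synthesis genes PYCR1, from 35.4 ± 4.15 to 80.7 ± 12.6 CPM (adjusted p = 0.00115), PSAT1, from 59.0 ± 8.17 to 113 ± 14.5 (0.00629), and PHGDH, from 152 ± 7.56 to 230 ± 14.3 (0.00652). The calls of PSAT1 and PHGDH ended without DMSO replicate 1 (0.0555 and 0.0635). Ribosomal protein genes were higher in 41 of 41, with a median of 0.44, 2 called and 35 adjusted over the list alone (adjusted p = 7.39e-22, or 0.294 with an estimated correlation). Their share of all counts was 1.73% ± 0.130 in DMSO and 2.339% ± 0.349 with parimifasor (SD, n = 3, exact permutation p = 0.1).

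Further lists were called higher in LN229, each only with the preset correlation (adjusted p = 0.245 to 0.762 with an estimated correlation). Hypoxia genes (17 of 20 higher, 2 called, adjusted p = 3.21e-05) and autophagy and lysosome genes (20 of 28 higher, 3 called, 0.00183) rose, the latter with SQSTM1, CTSD and WIPI1. Aminoacyl-tRNA synthetase genes (17 of 20 higher, 0.00154), amino acid transporters (7 of 11 higher, 0.0293, or 0.0525 with the block), glycolysis genes (13 of 21 higher, 0.022) and the ferroptosis list (11 of 16 higher, 0.0155) were called as well. In the last list the called members were FTL and FTH1, which store iron. The extracellular matrix list (15 of 25 higher, 0.00774) was called, too. Squamous differentiation genes (12 of 13 higher, 2 called, 7.29e-06), A549 markers (9 of 12 higher, 0.00378), fibroblast markers (8 of 12 higher, 0.04, or 0.124 with the block) and endothelial markers (7 of 10 higher, 0.0182) were higher too. The called members were LCN2 and SPRR2D in the first of these and AKR1C1 and AKR1C2 in the second. Squamous differentiation and endothelial genes were low, at mean log2 CPM of -1.9 to 0.651 and -1.33 to -1.06 in DMSO. Of 10 splits of LN229, 6 gave a camera p as small for glycolysis, 5 for squamous and 3 for fibroblast genes, the real one included. For squamous differentiation, synthetase, ferroptosis and matrix genes 2 did, the first at 1.02e-12 against 1.09e-06. For the other lists here the real split gave the smallest. The fibroblast marker THY1, at 0.157 ± 0.135 and 0.638 ± 0.318 CPM, lay within reach of KYSE140 reads, and without genes within reach the fibroblast adjusted p was 0.159. The squamous list (17 of 21 higher, 0.0128) had 15 genes within reach of KYSE140 reads, with a median log2 fold change of 0.25, against -0.07 for the 6 others, of which 4 were lower. Without genes within reach its adjusted p was 0.888. The mean log2 CPM of the 6 others was 3.47, 3.94 and 4.70 in DMSO replicates 1 to 3 and 4.66, 4.42 and 4.32 with parimifasor. That of the 15 within reach was 1.74, 1.97 and 2.39 in DMSO and 2.16, 2.54 and 2.36 with parimifasor. Adjusted over the list alone, the higher members numbered 5 of the autophagy and lysosome genes, 4 each of the amino acid transporters, glycolysis, ferroptosis, extracellular matrix and A549 lists, 3 each of the synthetases and endothelial markers, 2 each of the hypoxia, squamous differentiation and fibroblast lists and 1 of the squamous list.

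Mitotic genes fell in LN229, 37 of 37 being lower with a median of -0.44, 6 called over all genes and 26 adjusted over the list alone (adjusted p = 3.78e-26, or 0.245 with an estimated correlation). TOP2A went from 719 ± 1.12 to 474 ± 53.6 CPM (adjusted p = 0.0293) and KIF14, a kinesin outside the list, from 153 ± 4.81 to 98.1 ± 6.74 (0.00381). The TOP2A call ended without any LN229 library other than parimifasor replicate 1, at up to 0.16 without parimifasor replicate 2. DNA repair genes (22 of 26 lower, 2.42e-07), DNA replication genes (32 of 36 lower, 0.000124), histone genes (13 of 15 lower, 0.0112) and glioma markers (18 of 21 lower, 0.022) were lower too, with estimated-correlation adjusted p of 0.245, 0.598, 0.409 and 0.386. The histone genes were low in LN229 as well, with a mean log2 CPM of 0.253 to 1.15 per library. Of the 10 splits of LN229, 4 gave a camera p as small for histone and 3 for DNA replication genes, the real one included. For mitotic, DNA repair and glioma genes the real split gave the smallest. Adjusted over the list alone, 3 DNA repair genes and 2 glioma markers were lower.

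With an estimated correlation 20 of the 21 LN229 list calls were lost, at adjusted p of 0.245 to 0.762, while 8 lists had an unadjusted p below 0.05. After adjustment fry called 9 of the 21, namely NRF2 targets, amino acid synthesis, mitosis, integrated stress response, hypoxia, DNA repair, squamous differentiation, A549 markers, and autophagy and lysosome. Leaving out DMSO replicate 1 ended the calls of amino acid transporters (0.11), glycolysis (0.15), ferroptosis (0.0554), squamous (0.22), glioma (0.0505) and fibroblast genes (0.0706). Leaving out parimifasor replicate 3 ended those of amino acid transporters (0.133), glycolysis (0.873), ferroptosis (0.112), glioma (0.119) and A549 genes (0.0646). Without parimifasor replicate 2 the calls of DNA replication (0.174), histone (0.0982), squamous (0.0851), fibroblast (0.0971) and endothelial genes (0.0828) ended. Histone and glioma calls also ended without DMSO replicate 3 (0.202 and 0.0524) and the fibroblast call without DMSO replicate 2 (0.122). With the block, interferon-stimulated genes, lower in treated LN229, were called at 0.000203, and MAPK feedback genes, also lower, at 0.0334, with adjusted p of 0.682 and 0.398 with an estimated correlation in that fit. The interferon list fell in replicate 3 alone, where its mean log2 CPM was 7.26 in DMSO and 5.59 with parimifasor, against 2.52 and 2.49 in DMSO replicates 1 and 2 and 2.56 and 2.53 with parimifasor. With replicates 1 and 2 alone glycolysis (0.744), histone (0.0894), glioma (0.135) and amino acid transporter (0.0558) calls ended. Within replicate numbers 18 of the 21 lists moved in 1 direction in all 3 pairs. Mean log2 CPM of squamous differentiation genes changed by 3.11, 2.80 and -0.27 in replicates 1 to 3, that of squamous genes by 0.64, 0.54 and -0.13, and that of glycolysis genes by -0.023 in replicate 2. The length and GC correction ended the calls of glycolysis (0.105) and glioma (0.0682), and the CPM filter those of histone (0.16) and fibroblast genes (0.0612). In a fit of LN229 alone fibroblast (0.189) and endothelial (0.072) calls ended.

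**Figure D3:**
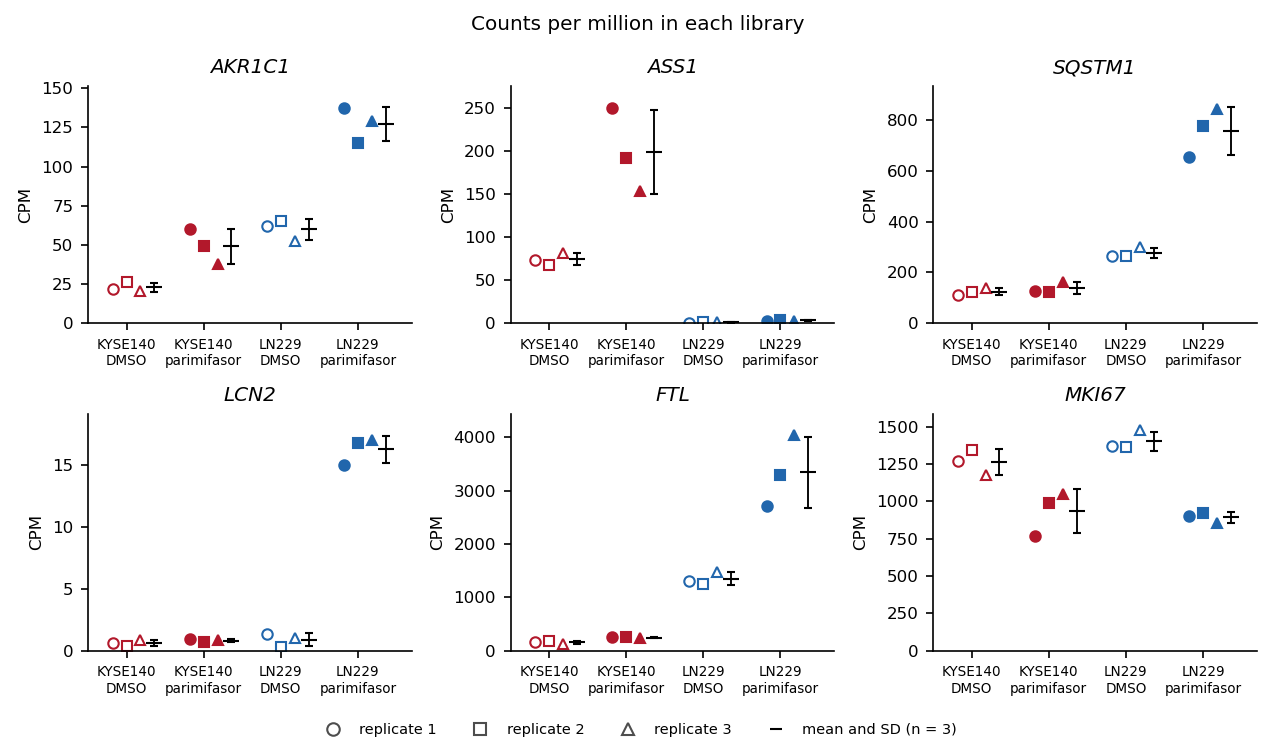
CPM of 6 genes in each library on a linear y axis from 0, by line and treatment, with symbols for the replicate number and bars for mean and SD (n = 3). SQSTM1 goes from 275 to 758 CPM in LN229 and is at 123 and 137 CPM in KYSE140, while AKR1C1 is higher in the treated libraries of both lines.

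Transcripts of the ATP synthase, the complex the compound has been described to act on, passed neither the list test nor the gene test in either line when all libraries were used. The 17 nuclear ATP synthase genes had median log2 fold changes of -0.03 in KYSE140 and 0.11 in LN229, with camera adjusted p of 0.687 and 0.266. Without KYSE140 DMSO replicate 3 the list was called lower in KYSE140 (0.00921), as it was with replicates 1 and 2 alone (0.00178), while without DMSO replicate 1, DMSO replicate 2 or parimifasor replicate 1 its direction turned (0.797, 0.592 and 0.991). ATP5F1B, the catalytic beta subunit, was at 835 ± 113 and 742 ± 73.4 CPM in KYSE140 (SD, n = 3, edgeR adjusted p = 0.736). The 13 mitochondrially encoded genes had medians of -0.01 and 0.14 and adjusted p of 0.832 and 0.172. In KYSE140 their mean was 0.03 and the test pointed up, against the sign of the median. In LN229 the list was called higher without DMSO replicate 1 (0.0261), without parimifasor replicate 3 (0.000313) and with replicates 1 and 2 alone (0.000514), and its direction turned without DMSO replicate 2 (0.897). MT-ATP6, which encodes an ATP synthase subunit, was at 2360 ± 346 and 2750 ± 508 CPM in LN229 (adjusted p = 0.706). Complex I genes had adjusted p of 0.904 and 0.453, genes of complexes II to IV 0.887 and 0.323, mitochondrial chaperones and proteases 0.832 and 0.274, the citrate cycle 0.438 and 0.366, and mitochondrial ribosomal proteins 0.208 and 0.278. Mitochondrial transcripts took 11.04% ± 1.54 of counts in KYSE140 DMSO and 12.5% ± 1.61 with parimifasor (exact permutation p = 0.4), and 5.964% ± 0.852 and 6.91% ± 1.49 in LN229 (exact permutation p = 0.4).

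The lists of p53 targets, pro-apoptotic genes and unfolded protein response genes were not called in either line. Their camera adjusted p in KYSE140 and LN229 were 0.832 and 0.123 for p53 targets and 0.0658 and 0.519 for pro-apoptotic genes. Unfolded protein response genes had 0.421 and 0.235. In all, 36 lists in KYSE140 (0.0658 to 0.963) and 26 in LN229 (0.0931 to 0.786) were not called. Median, mean and test differed in sign for 6 of these in KYSE140 (mitochondrially encoded, cholesterol, p53, extracellular matrix, epithelial-mesenchymal and squamous differentiation genes) and for 3 in LN229 (fatty acid, heat shock, and Wnt and Notch genes).

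The difference between the responses was tested as an interaction. LCN2 and SQSTM1 were the called genes, both raised more in LN229, with interaction log2 fold changes of -3.84 ± 0.555 and -1.31 ± 0.185 (SE, adjusted p = 0.0496 for each). In KYSE140 LCN2 was at 0.648 ± 0.242 and 0.825 ± 0.131 CPM (SD, n = 3) and SQSTM1 at 123 ± 13.2 and 137 ± 23.4. An unadjusted p below 0.05 was reached by 1237 genes, and with the block 8 genes were called, 3 with a positive and 5 with a negative difference, these 2 among them. Both calls lay at the threshold. Without LN229 parimifasor replicate 2 the adjusted p was 0.201 for each, and the count was 0 without any 1 of the KYSE140 DMSO replicates, KYSE140 parimifasor replicate 1, or LN229 parimifasor replicates 2 or 3, with 1022 to 1645 genes at an unadjusted p below 0.05. It was 1 without KYSE140 parimifasor replicates 2 or 3 or LN229 DMSO replicates 1 or 2, 7 without LN229 parimifasor replicate 1 and 10 without LN229 DMSO replicate 3.

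As groups, NRF2 targets (camera adjusted p = 9.24e-05), ribosomal proteins (9.25e-07), ribosome biogenesis (0.000168) and squamous differentiation genes (0.00655) had higher fold changes in LN229 than in KYSE140. These calls held without each library in turn, but not with an estimated correlation (adjusted p = 0.894 for each). Of 32 splits that part every numbered pair within each line, 8, 11, 7 and 16 gave a camera p as small for these lists in this order, the real one included. Integrated stress response (0.0166), amino acid synthesis (0.0155), mitochondrial ribosome (0.0481), pro-apoptotic (0.0294), extracellular matrix (0.0136), squamous (0.0155) and fibroblast genes (0.0136) also had higher fold changes in LN229. Mitotic (0.0283) and MAPK feedback genes (0.0205) had lower ones. Each of these 9 calls ended without 1 library or another, at up to 0.629 (integrated stress response, KYSE140 DMSO replicate 3), 0.122 (amino acid synthesis, KYSE140 parimifasor replicate 2), 0.421 (mitochondrial ribosome, LN229 parimifasor replicate 3), 0.214 (pro-apoptotic, the same library), 0.506 (extracellular matrix, KYSE140 parimifasor replicate 3), 0.173 (squamous, LN229 DMSO replicate 1), 0.0981 (fibroblast, KYSE140 parimifasor replicate 3), 0.969 (mitotic, the same library, with the direction turned) and 0.635 (MAPK feedback, the same library). With an estimated correlation the adjusted p was 0.894 for each of the 13, with 1 list below 0.05 unadjusted, and after adjustment fry gave 0.405 to 0.829, with 2 of them below 0.05 unadjusted. With the block the calls of mitochondrial ribosome (0.0843), mitotic (0.0667), pro-apoptotic (0.051) and fibroblast genes (0.051) were lost, and those of epithelial-mesenchymal (0.0492) and immediate early genes (0.00752) gained, the latter 2 at 0.819 and 0.863 with an estimated correlation in that fit. Without genes within reach of the other line's reads the calls of pro-apoptotic (0.0592), extracellular matrix (0.062) and fibroblast genes (0.112) ended, and the squamous list turned direction (0.806). With replicates 1 and 2 alone amino acid synthesis (0.113) and pro-apoptotic (0.278) calls ended and the mitotic list turned direction (0.341). The mitochondrial ribosome call also ended with RLE factors (0.0575) and with the length and GC correction (0.215).

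The calls of the lines overlapped in ASS1, AKR1C1 and AKR1C2, all higher in both, where 0.0328 genes would be expected of independent lists (Fisher's exact test, p = 3.46e-06). ASS1 lay within reach of KYSE140 reads in LN229, and without genes within reach the overlap was 2, AKR1C1 and AKR1C2 (0.0224 expected, exact p = 0.000197). Fisher's test takes genes as independent, but these 2 are neighbouring paralogs that can share reads. Both p-values can therefore overstate the overlap. With the block 41 genes overlapped, 35 higher (1.61 expected, exact p = 4.66e-37) and 6 lower (0.359 expected, exact p = 1.59e-06), and 1 gene was called in opposite directions. The overlap was 0 without KYSE140 DMSO replicate 1, parimifasor replicate 1 or parimifasor replicate 2, 1 without KYSE140 DMSO replicate 2, 10 without KYSE140 DMSO replicate 3 and 19 without KYSE140 parimifasor replicate 3. Of the LN229 calls, 111 of 122 had the same sign in KYSE140, and of the KYSE140 calls 8 of 10 had the same sign in LN229. Across genes, which are not independent replicates, the fold changes of the lines had a Pearson correlation of 0.104 and a Spearman correlation of 0.206.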

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

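The tests of other-line reads, the length and GC correction, the fit on replicates 1 and 2 alone, the comparison of spread and the splits were chosen only after the results had been seen.

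Each result here stood out because the lines responded differently in a direct test, an interaction for genes and camera on the interaction for lists, given as KYSE140 minus LN229. LCN2 (log2 difference -3.84, adjusted p = 0.0496) and SQSTM1 (-1.31, adjusted p = 0.0496) rose more in LN229. Lists with higher fold changes in LN229 were ribosomal proteins (adjusted p = 9.25e-07), NRF2 targets (9.24e-05), ribosome biogenesis (0.000168), squamous differentiation (0.00655), extracellular matrix (0.0136), fibroblast (0.0136), amino acid synthesis (0.0155), squamous (0.0155), integrated stress response (0.0166), pro-apoptotic (0.0294) and mitochondrial ribosome genes (0.0481). MAPK feedback (0.0205) and mitotic genes (0.0283) had lower fold changes in LN229. With an estimated correlation the adjusted p was 0.894 for each of these 13 lists. The gene count was 2 and ran from 0 to 10 without 1 library.

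The 2 genes and 13 lists were compared with 32 splits that, like the real one, part every numbered pair within each line. For the genes 7 of 32 splits gave as many, so chance is not excluded by them. All 6 others of these keep the LN229 libraries parted by treatment, with the labels as they are or exchanged, and so carry the response of LN229, a structure of the samples. The highest other count, 369, came from the split that exchanges all LN229 labels, which measures the mean response of the lines. The 25 remaining splits called 0 genes. For the lists 16 of 32 splits gave as many and the highest other gave 25, so chance cannot be excluded there either. The real split gave the smallest camera p for 1 of the 13 lists. In 20 drawn splits that part fewer pairs, camera called up to 24 lists and edgeR no difference gene. In the 6 splits of KYSE140 that part fewer pairs, with LN229 parted by treatment, edgeR called up to 36 difference genes, the 36 with DMSO replicates 2 and 3 and parimifasor replicate 3 against the rest, and these splits again carry the response of LN229.

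The first pattern is that squamous markers were higher in treated LN229 and glioma markers lower in treated KYSE140. For LCN2 and SPRR2D the levels argue against reads of KYSE140, since in treated LN229 they stood at 2010% and 10700% of those in treated KYSE140. For the squamous list in LN229 such reads cannot be told apart from a rise of the cells' own transcripts. Without genes within reach only 6 genes were left, with a camera adjusted p of 0.888 and a median log2 fold change of -0.07, against 0.25 within. But the mean log2 CPM of these 6 went from 3.47 and 3.94 to 4.66 and 4.42 in replicates 1 and 2 and from 4.70 to 4.32 in replicate 3. That of the genes within reach went from 1.74 and 1.97 to 2.16 and 2.54 and from 2.39 to 2.36. For the glioma list in KYSE140 reads of LN229 cannot be told apart from a fall of the cells' own transcripts, since the adjusted p became 0.187 with fewer genes, and the genes within reach went from a mean log2 CPM of 0.251 to -2.24 in replicate 3 but from 0.216 and 0.249 to 0.516 and 0.144 in replicates 1 and 2, while those outside, called CDH2 among them, fell on average in each replicate, with a median log2 fold change of -0.24 (-0.47 within). The share of other-line reads was 0.729% in DMSO and 0.931% with parimifasor in LN229 (exact p = 0.3) and 0.846% and 0.649% in KYSE140 (exact p = 0.5), where parimifasor replicate 3 alone was low (0.204%, with a treated mean of 0.87% and a glioma adjusted p of 0.621 without it), so a change of that share stays open, as do how these reads arose, which was not tested, and a response of the cells to parimifasor.

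The second pattern is that ribosomal protein genes were higher in treated LN229, a call lost with an estimated correlation (adjusted p = 0.294). Against gene length as the whole cause, the list median of 0.437 lay at percentile 100 among 10000 random lists matched on length and expression, with the middle 95% of these ending at 0.00967. The random lists drew their genes singly, so this range does not allow for genes that vary together. Against length and GC content together, the median after a correction was 0.387 (adjusted p = 9.75e-26). Against the replicate 3 libraries as the whole cause, replicates 1 and 2 alone gave a median of 0.317 (camera adjusted p = 5.19e-16). Within replicate numbers 1 to 3 the mean log2 CPM rose by 0.432, 0.225 and 0.596, most in replicate 3. These adjusted p rest on the preset correlation, with which another split of LN229 gave this list an unadjusted camera p of 4.29e-15. They therefore do not exclude chance. Reads shared with pseudogenes and RNA quality were not tested and stay open beside a response to parimifasor.

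The third pattern is that edgeR called 10 genes in KYSE140 (0 to 116 without 1 library) and 122 in LN229 (35 to 148). A larger spread in KYSE140 cannot be told apart from an equal one, because the biological coefficient of variation was 22.8% (20.1% to 25.1% without 1 library) in KYSE140 and 20.6% (17% to 22.6%) in LN229, and these ranges overlap. The replicate 3 libraries are a candidate explanation for part of it, since replicates 1 and 2 alone gave 838 genes in KYSE140 and 395 in LN229, with a coefficient of variation of 12.3% in each. With the replicate block, which also takes out a shift shared by both treatments, KYSE140 still had fewer calls, 217 against 350, or 324 against 425 with the length and GC correction added. Whether KYSE140 responds more weakly stays open.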

How the results depend on the processing

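The mean response over both lines, the length and GC correction with or without the block, replicates 1 and 2 alone and leaving out genes within reach of the other line's reads were chosen only after the data had been seen. The other settings were chosen before.

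The baseline difference stayed within 1.5 times its count in every setting run for it (11479 to 14372). For KYSE140 genes (10) the count was 375 with no filter, 322 with DESeq2, 217 with the replicate block, 28 by limma-trend on FPKM with no filter, 6 with the length and GC correction, 324 with this and the block, and 838 with replicates 1 and 2 alone. It was 0 by limma-trend with pseudocounts of 1 and 0.1 (1875 and 1744 genes at an unadjusted p below 0.05) and by edgeR on the line alone (1688), and 10 by limma-voom. At 2-fold (5) the same settings gave 117, 56, 36, 1, 3, 38 and 102, and 0 where the count above was 0. For LN229 genes (122) the count was 724 with no filter, 482 with DESeq2, 350 with the block, 425 with block and correction, and 395 with replicates 1 and 2 alone. At 2-fold (63) it was 292 with no filter, 133 with DESeq2, 101 with the block, 21 by limma-trend with a pseudocount of 1, 17 by this with no filter, and 146 with replicates 1 and 2 alone. Genes that differed in response (2) numbered 190 with no filter, 63 with DESeq2, 8 with the block, 8 by limma-trend with no filter, 51 with block and correction, 64 with replicates 1 and 2 alone, and 1 with upper quartile factors and 1 with the correction. They numbered 0 by edgeR with RLE factors (1229 unadjusted) or a filter of 1 CPM (950), by limma-voom (1087) and by limma-trend with a pseudocount of 0.1 (818).

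The mean response (369) gave 1129 with no filter, 1059 with DESeq2, 1046 with the block, 148 by limma-trend with no filter, 1115 with block and correction and 1164 with replicates 1 and 2 alone. The overlap (3) was 67 with DESeq2, 41 with the block, 49 with block and correction, 79 with replicates 1 and 2 alone, and 0 at an adjusted p of 0.01 and 0 with each line fitted alone. With an estimated correlation camera called 0 lists in KYSE140, 1 in LN229, 0 for the difference and 0 for the mean response (2, 8, 1 and 9 unadjusted). Filters change the genes tested, and replicates 1 and 2 alone the libraries. For the rest the cause was not tested.

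Without 1 library at a time, KYSE140 genes ran from 0 (DMSO replicate 1 or parimifasor replicate 1 out) to 116 (parimifasor replicate 3 out), at 2-fold 0 to 34 in the same refits. LN229 genes ran from 35 (DMSO replicate 1 out) to 148 (parimifasor replicate 1 out), at 2-fold 30 to 82. Difference genes ran from 0 to 10, the mean response from 159 (KYSE140 DMSO replicate 2 out) to 560 (KYSE140 parimifasor replicate 3 out), the baseline from 12824 to 13381 and the overlap from 0 to 19. Lists called ran from 10 to 21 in KYSE140, 17 to 22 in LN229, 8 to 16 for the difference and 16 to 23 for the mean response. All 12 refits keep at least 2 libraries per group.

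Directions turned in these cases, for which the cause was not tested. Mitochondrially encoded genes turned in KYSE140 without DMSO replicate 2 (adjusted p = 0.817), DMSO replicate 3 (0.739) or parimifasor replicate 2 (0.567), in a range of 0.377 to 0.817 without 1 library. They turned in LN229 without DMSO replicate 2 (0.897, range 0.000313 to 0.897). For the difference they turned with the correction (0.858), with block and correction (0.908) and without LN229 DMSO replicate 2 (0.813) or LN229 parimifasor replicate 2 (0.944, range 0.0118 to 0.992). ATP synthase genes turned in KYSE140 with the correction (0.968), with block and correction (0.984) and without DMSO replicate 1 (0.797), DMSO replicate 2 (0.592) or parimifasor replicate 1 (0.991, range 0.00921 to 0.991). Ribosomal proteins in KYSE140 (0.844) and mitotic genes for the difference (0.341) turned with replicates 1 and 2 alone, and the latter also without KYSE140 parimifasor replicate 3 (0.969, range 0.000197 to 0.969). The squamous list turned without genes within reach, in LN229 (0.888) and for the difference (0.806). ATP5F1C turned in KYSE140 with the correction (log2 fold change 0.0092) and with block and correction (0.012).

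Called named genes kept call and direction in 130 of 220 values in KYSE140, 784 of 965 in LN229, 25 of 54 for the difference and 610 of 646 for the mean response, and the others lost the call in the same direction. Called lists kept both in 154 of 176, 279 of 335, 209 of 273 and 292 of 314. The replicate block ended no call of these genes. It ended 2 list calls in LN229 and 4 for the difference, added 2 each in KYSE140, LN229 and the difference and 3 for the mean response, and changed no other list call. In simulated data, which held no replicate effect, it called 12 and 19 unchanged genes in the lines, against 9 in each without it. At a depth of 34.38 to 49.24 M counts, a gene without counts in a library is excluded only down to 3 counts of that total. Simulated 1.5-fold changes were recovered in 17.9% (KYSE140) and 14.9% (LN229) of cases, so changes of this size were mostly missed.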

Other observations

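The mean response over both lines, the genes named for it and the splits were chosen only after the data had been seen.

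Averaged over both lines, parimifasor changed 369 genes, 246 higher and 123 lower, of which 256 were called in neither line alone. The count was 211, 159, 181 and 560 without KYSE140 DMSO replicate 1, DMSO replicate 2, parimifasor replicate 1 and parimifasor replicate 3, in this order, and 163, 163, 245, 182 and 232 without LN229 DMSO replicates 1, 2 and 3 and parimifasor replicates 2 and 3. Genes were named by the rule used for the lines, applied to both at once. PCK2, the mitochondrial form of PEP carboxykinase, was at 122 ± 27.4 and 252 ± 40.4 CPM in DMSO and parimifasor in KYSE140 and at 15.3 ± 1.41 and 33.6 ± 7.18 in LN229 (SD, n = 3; mean log2 fold change 1.09 ± 0.126 SE, edgeR adjusted p = 0.000731). NGFR, a neurotrophin receptor gene, was at 32.6 ± 6.23 and 68.0 ± 2.26 CPM in KYSE140 and at 52.3 ± 7.89 and 121 ± 37.0 in LN229 (1.13 ± 0.133, adjusted p = 0.000804). Also higher were UNC5B, BEX2, VEGFA, ABCC3, RCN3 and FTL, by 1.96-fold to 3.91-fold. ASNS rose too (1.38 ± 0.274, adjusted p = 0.0313), but without 1 library its call held only when KYSE140 DMSO replicate 2 or 3, KYSE140 parimifasor replicate 2 or LN229 parimifasor replicate 1 was out, and the adjusted p reached 0.104 without LN229 DMSO replicate 1. The filaggrin gene FLG was at 14.6 ± 3.04 and 8.52 ± 1.65 CPM in KYSE140 and at 8.80 ± 1.67 and 4.64 ± 0.590 in LN229 (-0.85 ± 0.152, adjusted p = 0.0107), and SOX5 was lower by 1.53-fold (adjusted p = 0.0144). ASPM, CENPE, TOP2A, CENPF, KIF18A, MKI67, KIF4A and KIF14 were lower, with log2 fold changes of -0.59 to -0.51. HOXB9 and the pseudogene HMGB1P6 met the naming rule too. The HOXB9 call held only without KYSE140 DMSO replicate 3 or LN229 parimifasor replicate 1, with an adjusted p of up to 0.108 (without LN229 DMSO replicate 1). The HMGB1P6 call ended without DMSO replicate 1 or 2 of KYSE140 or of LN229, or parimifasor replicate 1 or 2 of LN229, at up to 0.0972 (KYSE140 DMSO replicate 2). Of the 24 genes that met the rule, the other 21 kept their calls without each library in turn.

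By camera, mitotic genes were lower in the mean response, 37 of 37 with a median log2 fold change of -0.40, 19 called over all genes and 33 adjusted over the list alone (adjusted p = 3.81e-28, or 0.247 with an estimated correlation). Integrated stress response genes were higher in 23 of 23 (median 0.50, 3 called, 12 adjusted over the list alone, adjusted p = 1.03e-11, or 0.247 with an estimated correlation). NRF2 targets were higher in 21 of 22 (median 0.33, 6 called, 13 adjusted over the list alone, adjusted p = 4.43e-12, or 0.0851 with an estimated correlation), and ribosomal proteins in 41 of 41 (median 0.30, 6 called, 32 adjusted over the list alone, adjusted p = 1.35e-16, or 0.38 with an estimated correlation). These calls held without each library in turn. In all, 15 of 47 lists were called, 10 higher and 5 lower, and fry called 7 of the 15. With an estimated correlation all 15 calls were lost, at adjusted p of 0.0851 to 0.648. Among 32 splits that part every numbered pair, the real one gave the smallest camera p for 2 of the 15 lists, aminoacyl-tRNA synthetase and DNA repair genes. A p as small came from 2 splits each for mitotic, integrated stress response and NRF2 genes, the real one included. For ribosomal proteins 5 splits gave one as small. Unadjusted camera p of mitotic genes was 9.41e-38 in another split against 8.12e-30 in the real one. With the block, unfolded protein response genes (adjusted p = 0.0343), interferon-stimulated genes (0.0031) and YAP targets (0.0412) were called too, all lower. Their estimated-correlation adjusted p in that fit were 0.789, 0.87 and 0.46. The interferon-stimulated genes fell in replicate 3 alone, from a mean log2 CPM of 4.57 to 3.65 in KYSE140 and of 7.26 to 5.59 in LN229. In replicates 1 and 2 they went from 0.697 and 0.687 to 1.01 and 0.735 in KYSE140 and from 2.52 and 2.49 to 2.56 and 2.53 in LN229.

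The counts were compared with those of other splits of the libraries. For the mean response 1 of the 32 splits that part every numbered pair, the real one, gave 369 genes or more, and the highest other gave 18. A share of 1 in 32 is the smallest these splits can give, and the contrast and splits were chosen after the data had been seen. The labels also do not say that equal numbers are pairs, so chance is made less likely but is not excluded. Among the 6 splits of KYSE140 that part fewer pairs, with LN229 parted by treatment, the highest count was 112, with DMSO replicate 3 and parimifasor replicates 1 and 3 against the rest. That split carries the response of LN229 and has both KYSE140 replicate 3 libraries on 1 side. For its 15 lists 10 of 32 splits gave as many and the highest other gave 25, so chance cannot be excluded. The overlap of 3 genes was reached by 1 of 32 splits, the real one, and the highest other gave 0, but the others could give no overlap. In 30 of the 31 others a line had no call, and the last exchanges the labels of LN229 alone, so these splits say nothing about chance. All 32 splits part every numbered pair within each line.

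A single line has 10 splits, too few for a share under 0.05. KYSE140 gave 10 genes in the real split and 10 in the highest other (reached by 2 of 10 splits), and 5 and 5 at 2-fold (2 of 10). That other split sets DMSO replicate 3 and parimifasor replicates 1 and 3 against the rest, with both replicate 3 libraries on 1 side, and with the block the real split gave 217. KYSE140 lists numbered 11 in the real split and 22 in the highest other (7 of 10). LN229 gave 122 genes, 63 at 2-fold and 21 lists in the real split, against 0, 0 and 20 in the highest other (1 of 10 for each). The real split gave the smallest camera p for 12 of the 21 LN229 lists. For the lines in DMSO the real split gave 13757 and the highest other 0 (1 of 10). Of the 10 splits in a line, 4 part every numbered pair, again too few, and the others place both libraries of a number on the same side. Among the 4, the real and highest other counts were 10 and 0 genes and 11 and 15 lists in KYSE140, 122 and 0 genes and 21 and 16 lists in LN229, and with the block 217 and 0 genes in KYSE140 and 350 and 0 in LN229.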
